A study of Homo sapiens with 22 samples.

How the data were processed

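RNA was sequenced from 11 established human glioblastoma cell lines without treatment, with 2 libraries per line and 22 libraries in all. Per the labels' protocols, cells were grown in serum, in DMEM (A-172, KNS-42, LN-18, LN-229), EMEM (AM-38, T98G, U-138MG, U-87MG) or RPMI medium (KALS-1, SNU-466, SNU-1105), with 20% serum for AM-38 and 10% for the other lines, and libraries were strand-specific and made from poly(A) RNA. Whether the 2 libraries of a line came from separate cultures is not stated, so p-values measure the spread between these libraries, which may be technical.

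The authors deposited, per gene and library, raw read counts, FPKM and the gene length behind them, in a table of 2221 genes for 8 lines and a table of 5383 genes for 3 lines (A-172, AM-38, SNU-466). The deposited FPKM relate the reads to that length and to the library total. Per the submitters' processing notes, cutadapt 1.9.1, FastQC 0.10.1, HISAT2 2.2.1, HTSeq 0.6.0 and StringTie 1.3.3 were used with the hg38/GRCh38 build, with no role given to each tool; the annotation release is not given in the sources used here. How the genes of each table were chosen is not stated. Of the 2221 genes, 99.3% had mean FPKM that differed 2-fold or more between KALS-1, LN-18 and T98G on one side and the other 5 lines on the other, more than in any other of the 127 splits of the 8 lines (next, 88.2%). Among the genes of the 3-line table, 93.9% differed 2-fold or more between SNU-466 and the other lines (next, 69.5%). The listed genes were therefore treated as chosen on these samples: counts are of listed genes, not a share of the transcriptome, and adjusted p-values cover listed genes only. The split of the 8 lines was used in no comparison, whereas that of the 3 lines is the comparison of SNU-466 with the other lines, so the high counts of SNU-466 may follow in part from the choice of genes. KALS-1, LN-18 and T98G are each set against a mean that lies mostly on the other side of their split, where 40.4% of genes are higher on their side, so their counts and balance may be affected too.

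The total of each library was computed as the reads of a gene divided by its length and its FPKM, in matching units, over genes with at least 20 FPKM and 200 reads. Genes of a library gave the same total within 0.0219%, and for at least 99.9% of genes the total gave back the deposited FPKM within 0.01. The listed genes held 5.81% to 10.2% of the total in the 8-line table and 21.8% to 37.1% in the 3-line table. Levels are reads scaled to these totals (CPM), as mean ± SD over the 2 libraries of a line. A count of 0 in a library allows up to 3 reads, which is 0.141 to 0.177 CPM; such floors cover counting error only. Where all compared libraries of a line or group were at 0, a fold is a lower bound against 3 reads over that group. Gene names matched for 2220 of 2221 and 5382 of 5383 genes, and coordinates are from GENCODE 29 on GRCh38.

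The tables were fitted apart, each with 1 coefficient per line, using the edgeR 4.0.16 quasi-likelihood test on counts with the totals above. The planned TMM scaling was replaced, because TMM assumes that most genes do not differ and these genes appear chosen for differing; TMM and RLE factors of the listed genes were alternatives. After the low-count filter by line, 2095 and 5035 genes were tested for any difference among lines (with line means at least 1 apart on the log2 scale), and for each line against the equally weighted mean of the other lines on the log scale (called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1). That mean has no finite value where another line had 0 reads in both libraries, which held for 680 to 752 of the tested genes per line in the 8-line table and 302 to 929 in the 3-line table. For 246 to 359 and 24 to 179 of these genes edgeR returned a p above 0.9, mostly where the line was itself at or near 0 reads, so the counts of lower genes can miss such genes. Genes called higher also included 69 to 204 per line in the 8-line table that lay under the arithmetic mean of the other lines, and 0 to 213 in the 3-line table. limma 3.58.1 on log2 CPM with a prior count of 2, which stays finite, was therefore added after the data were seen, and its counts of lower genes are given beside those of edgeR.

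The gene lists (24), the rule for named genes and the other tests were fixed before the data were examined. Fisher's exact test of how many genes of a list were included was not among them. Per line, the rule names the 5 called genes with the largest rise whose libraries exceed every other library, at 10 CPM or more, and the 3 with the largest fall. Among lines it names the 20 genes with the largest range, and of each list at most 4 members per line; genes with near-identical copies are marked uncertain. Lists with at least 3 tested members were tested with limma camera on log2 CPM (preset correlation 0.01, two-sided, adjusted over all lists and lines of a table), with an estimated correlation and fry as alternatives. For culture medium, 1 summed count per line was tested with edgeR for EMEM against DMEM. The 3 planned correlations of list scores were not run: of the genes they need, the cell cycle list had 0 and the proneural list 1 in the 8-line table, and genes that appear chosen on a split of these lines cannot give an unbiased relation. Other alternatives were DESeq2 1.42.0, no low-count filter, a filter at 5 CPM in 2 libraries, a fit of all 11 lines on the 779 genes of both tables, the replicate number as a block and each library left out in turn. Alternatives added after the data were seen were TMM on the listed genes, limma on log2 CPM and a fit without T98G.

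Scripts were tested on simulated data with the totals of these libraries and, in every line, each gene's mean over all libraries. For the tests of a line, only the changed genes and a raised list differed, in 1 line. Genes at 0 reads in 1 line and high in others were thus not simulated, so recovery of such genes was not tested. For KALS-1 against the other lines (1874 genes), edgeR recovered 50.8% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold, and called 5 of 1661 unchanged genes. For A-172 (4776 genes) it recovered 41.8%, 100% and 100%, and called 2 of 4559 unchanged genes. A list raised 4-fold was recovered by camera in both tables (adjusted p = 6.38e-19 and 3.05e-41), also with an estimated correlation (adjusted p = 0.00192 and 0.0171), and 0 of 80 and 0 of 57 tests of other lists were called. The list raised in 1 line was also called in 6 of the other lines of the 8-line table and in the other 2 of the 3-line table, since each line is set against a mean that holds the raised line. With the spread of the real lines, the medium test recovered 0 of 100 genes changed 64-fold, and with a biological coefficient of variation of 0.2 it recovered 100 of 100. Replicates correlated at a Pearson r of 0.978 to 0.998 over log2 CPM, and no pair agreed within sampling noise (chi-square per gene of 2.24 to 186). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used.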

Results

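Poly(A) RNA of 11 established glioblastoma cell lines, grown in serum without treatment, was measured by RNA-seq in 2 libraries per line. Expression was compared among the lines and for each line against the others, separately for 8 lines (U-87MG, U-138MG, T98G, LN-18, LN-229, KNS-42, KALS-1, SNU-1105; 2221 genes) and 3 lines (A-172, AM-38, SNU-466; 5383 genes). How the genes of each table were chosen is not stated, and nearly all differ between sets of these lines, so the counts below describe the listed genes. Unless stated otherwise, a level is the mean ± SD over the 2 libraries of a line in CPM (reads scaled to the library total), and p-values are Benjamini-Hochberg adjusted. The SE of a log2 fold change was worked back from the F statistic of the edgeR test.

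GREM1, a secreted BMP antagonist, stood at 1753 ± 167 CPM in KNS-42 and 0.0584 CPM in KALS-1, and A2M, a plasma protease inhibitor, at 1392 ± 193 CPM in KNS-42 and 0 reads in U-87MG. SOX2, a transcription factor of neural stem cells, reached 800 ± 24.8 CPM in KNS-42 and 0.0265 CPM in T98G. IGFBP5, which binds insulin-like growth factors, was at 9796 ± 2861 CPM in T98G and 3.13 ± 0.0843 CPM in U-87MG. PDGFRA, a receptor tyrosine kinase, was at 1179.9 ± 17.3 CPM in U-138MG and 0.288 CPM in KALS-1. The long noncoding RNA FENDRR reached 331 ± 0.928 CPM in LN-18, and LRRC15 360.2 ± 128 CPM in U-87MG. These genes are among the 20 with the largest range over the 8 lines. Of 2095 tested genes, 2089 differed among the 8 lines (edgeR quasi-likelihood test), and the line means of 2039 spanned at least 2 on the log2 scale and those of 968 at least 5.

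KALS-1 stood apart in interferon response genes. Of the 13 listed members of the interferon list, 12 rose in KALS-1, both over all genes and adjusted over the list alone. Nearly all listed genes differ 2-fold or more between KALS-1, LN-18 and T98G and the other lines. The choice of genes may thus favour interferon genes that are high in KALS-1, and only 13 of the 20 genes of the list were included. This limits both the count and the list test below. IFI6 reached 1314 ± 5.50 CPM (log2 fold change 6.56, SE 0.12), MX1 621 ± 1.3 CPM (6.91, SE 0.12), OAS3 511 ± 13.3 CPM (3.54, SE 0.11) and IFI27 745 ± 25.1 CPM, where the highest other line was at 0.806 CPM (11.13, SE 0.17). XAF1 was at 0.292 ± 0.165 CPM in KALS-1 and 10.3 ± 4.20 CPM in T98G. The chemokine gene CCL5 (chromosome 17, 35871491 to 35880793) was at 91.3 ± 0.230 CPM with 10 reads in the 14 libraries of the other lines. NPPB, the precursor of B-type natriuretic peptide, was at 49.0 ± 2.57 CPM, ELSPBP1 at 36.8 ± 0.718 CPM and TSPYL5 at 25.4 ± 0.403 CPM. Adjusted p-values of these 5 rule-selected genes (IFI27, CCL5, NPPB, ELSPBP1, TSPYL5) ran from 1.04e-19 to 2.97e-12. The class I gene HLA-C, whose reads can be shared with its paralogs, rose to 664 ± 13.2 CPM and the immunoproteasome gene PSMB9 to 49.2 ± 0.896 CPM, while the Wnt receptor FZD6 fell to 0.190 CPM (76.9 CPM over the other lines) and ENPP2, the autotaxin gene, to 0.160 CPM (69.0 CPM). Of 4 immune cell genes, CD14 (10.4 ± 0.551 CPM) and PTPRC (5.96 ± 0.0893 CPM) rose in KALS-1, CSF1R (1.31 ± 0.453 CPM) and ITGAM were not called (camera adjusted p = 0.344), and CD74 was at 0.233 ± 0.247 CPM. In the camera test the interferon list was higher in KALS-1 (adjusted p = 5.23e-08), a call not kept with an estimated correlation (adjusted p = 0.116).

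**Figure D1:**
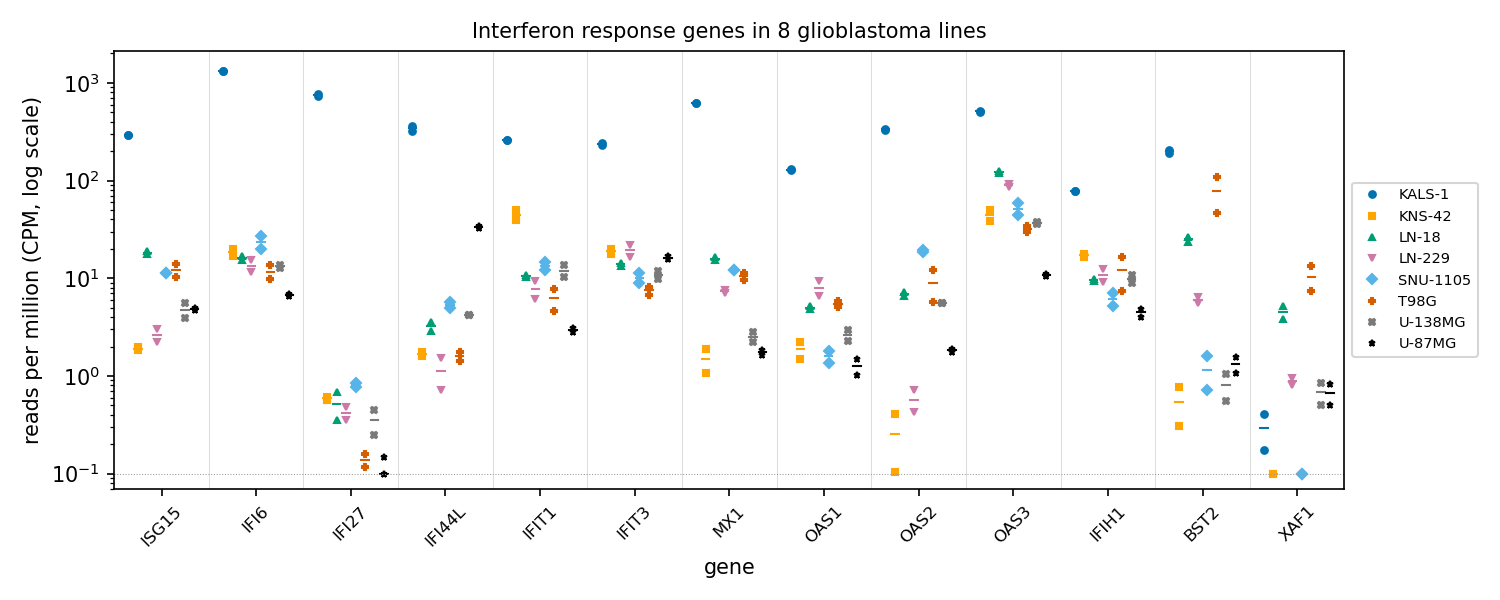
CPM (log scale) of the 13 interferon response genes in the 8 lines, with 1 point per library and a short bar at the mean of the 2 libraries of a line; values under 0.1 CPM are drawn at 0.1. KALS-1 lies above the other lines for 12 genes, with IFI6 at 1314 CPM, and below 5 of them for XAF1 at 0.292 CPM.

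U-87MG showed low interferon genes and high cytokine genes. In U-87MG 10 of 13 interferon genes fell, among them OAS3 at 10.8 ± 0.519 CPM and IFI6 at 6.74 ± 0.211 CPM (camera adjusted p = 0.0309, and 0.509 with an estimated correlation). IFI44L rose to 33.5 ± 0.936 CPM against the log-scale mean of the other lines. It lay under their arithmetic mean, which rests on KALS-1 (323 and 365 CPM in its libraries). The mean of the other lines includes KALS-1, and in simulated data a rise of the interferon list in KALS-1 alone called it in 6 other lines. Of 7 inflammatory cytokine genes, 6 rose, with LIF at 377 ± 151 CPM, CXCL3 at 115 ± 44.1 CPM and TNFAIP3 at 63.9 ± 11.9 CPM, and CCL2 fell to 0.815 CPM (camera adjusted p = 0.0879, not called). IL36B, a cytokine of the interleukin 1 family, was at 143 ± 60.0 CPM against at most 1.27 CPM elsewhere. Other rule-selected genes were DCC, a netrin receptor (45.0 ± 11.0 CPM), the adenylate cyclase ADCY8 (105 ± 5.43 CPM), EBF2 (114 ± 17.5 CPM) and HLA-DRB5 (110.1 ± 5.09 CPM), the last uncertain because its paralogs share reads. A2M had 0 reads in U-87MG, at least 3096-fold below the mean of the other lines. That mean rests on KNS-42 and LN-229 (203 CPM), with at most 3.38 CPM in the other 5. ADAMTS15 had 1 read in U-87MG against 87.3 CPM over the other lines, from 1.77 CPM in LN-18 to 480 CPM in KNS-42.

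MHC class II genes divided the lines by level. Of 7 antigen presentation genes, 5 rose in LN-229, KNS-42 and U-87MG, while HLA-C fell in LN-229 and U-87MG and PSMB9 in KNS-42 and U-87MG. CD74, the invariant chain, was at 2029.9 ± 332 CPM in LN-229 (log2 fold change 8.75, SE 0.15), 399 ± 37.2 CPM in KNS-42 (6.07, SE 0.15) and 269 ± 17.7 CPM in U-87MG (5.42, SE 0.15), and at or under 2.79 CPM in the other 5 lines. CIITA, the transactivator of class II genes, was at 131 ± 4.46, 91.4 ± 25.0 and 41.6 ± 1.58 CPM in the same lines. U-138MG differed in that HLA-DRA (29.1 ± 6.98 CPM), HLA-DPA1 (34.3 ± 2.52 CPM) and CIITA (25.8 ± 5.47 CPM) rose while CD74 fell (1.48 ± 0.259 CPM). These rises are against the log-scale mean of the other lines. The levels lie under the arithmetic mean of those lines and under the levels in LN-229, KNS-42 and U-87MG. CD74 in U-87MG likewise lies under the arithmetic mean of the lines it was compared with. In KALS-1, HLA-DRA had 1 read in both libraries together. The camera test called the antigen presentation list in none of the 8 lines (adjusted p = 0.0860 in LN-229 and 0.102 in KNS-42), and reads of HLA-DRA, HLA-DRB1 and HLA-DPA1 can be shared with paralogs.

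**Figure D2:**
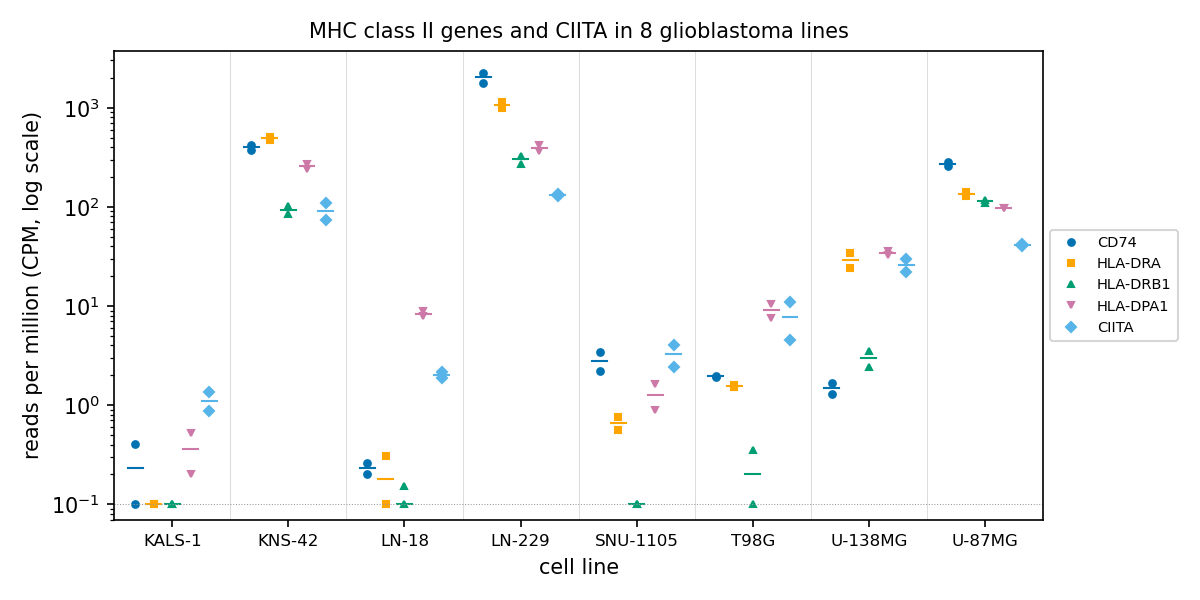
CPM (log scale) of the class II genes CD74, HLA-DRA, HLA-DRB1 and HLA-DPA1 and of their transactivator CIITA in the 8 lines, with 1 point per library and a short bar at the mean of the 2 libraries; values under 0.1 CPM are drawn at 0.1. LN-229, KNS-42 and U-87MG lie highest (CD74 at 2029.9, 399 and 269 CPM), and in U-138MG CD74 (1.48 CPM) lies below CIITA (25.8 CPM).

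KNS-42 was highest for SOX21, a transcription factor gene of neural progenitors, at 299 ± 9.58 CPM (7.12 CPM in SNU-1105, the next line), and for the oncogene MYCN at 164 ± 21.0 CPM (11.0 CPM in LN-229). ITIH5 was at 440 ± 13.6 CPM and MMRN1 at 101 ± 21.7 CPM. Adjusted p-values of these genes and GREM1 ran from 3.29e-19 to 1.15e-13. GAP43, a growth cone protein, stood at 221 ± 32.7 CPM in KNS-42 and 24.2 ± 5.94 CPM in SNU-1105, and the synaptic gene SYT1 at 40.6 ± 1.31 CPM in LN-229, 35.0 ± 5.02 CPM in KNS-42 and 26.8 ± 2.68 CPM in U-87MG. FLI1 had 0 reads in KNS-42, at least 137-fold below the mean of the other lines, and KCNE4 had 3 reads against 71.2 CPM. The mean of FLI1 rests on KALS-1, LN-18, SNU-1105 and T98G (16.3 to 23.0 CPM in their libraries). Each library of LN-229, U-138MG and U-87MG was at most at 0.66 CPM, so a level near 0 was not particular to KNS-42. In LN-229 the basement membrane gene FREM2 reached 337 ± 74.7 CPM, the integrin gene ITGA9 104 ± 18.5 CPM, HLA-DQA1 79.6 ± 21.0 CPM and FAM135B 14.0 ± 0.645 CPM, while TUBA3C (25.8 ± 1.84 CPM) is uncertain because of near-identical tubulin genes. CHI3L1 had 1 read in LN-229, SLPI had 0 (61.4 CPM in T98G, 7.50 CPM in LN-18 and at most 0.740 CPM in the others), and 4 of 6 mesenchymal genes fell.

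FN1, the fibronectin gene, reached 14748 ± 645 CPM in U-138MG and 11243 ± 872 CPM in SNU-1105, and FBN1, the fibrillin gene, 3935 ± 413 and 1537 ± 51.6 CPM. All 3 listed matrix genes rose in U-138MG, and FN1 and FBN1 rose in SNU-1105 and U-87MG (4064.8 ± 278 and 834 ± 129 CPM). The list was called in none of these lines (camera adjusted p = 0.0879, 0.0879 and 0.736). In U-87MG the rises are against the log-scale mean, and both levels lie under the arithmetic mean of the other lines. In SNU-1105, CHI3L1 was at 455 ± 28.0 CPM, the Wnt modulator SFRP2 at 308 ± 138.5 CPM, the sulfatase gene SULF1 at 171 ± 73.1 CPM, the VEGF receptor gene KDR at 79.2 ± 27.9 CPM and C11orf87 at 52.0 ± 4.04 CPM. U-138MG was highest for the homeobox gene MEOX2 (121 ± 4.74 CPM), FAM180A (163 ± 2.24 CPM), ELFN1 (93.2 ± 19.6 CPM), the ephrin receptor gene EPHA7 (49.8 ± 3.98 CPM) and the prostacyclin synthase gene PTGIS (48.2 ± 7.13 CPM). Adjusted p-values of the rule-selected genes ran from 6.69e-16 to 1.88e-13 in SNU-1105 and from 1.39e-16 to 1.38e-13 in U-138MG. FOXF1 fell to 2 reads and KRT18 to 0.276 CPM in U-138MG, with KRT18 at 0.345 CPM in U-87MG. In SNU-1105 TNXB fell to 1.13 ± 0.0479 CPM (35.4 CPM over the other lines). That mean rests on U-138MG (141 CPM) and U-87MG, with each library of the remaining lines at or under 6.92 CPM.

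All 4 listed genes of simple epithelia rose in LN-18 and KALS-1. Nearly all listed genes differ 2-fold or more between these lines with T98G and the other 5, so the table may favour genes that these lines share. Levels included KRT18 at 205 ± 12.2 CPM in LN-18 and 180.2 ± 10.7 CPM in KALS-1, KRT8 at 154 ± 1.73 and 56.1 ± 1.51 CPM and CDH1, the E-cadherin gene, at 8.07 ± 0.105 and 9.54 ± 0.288 CPM, while KRT19 was at 1.44 ± 0.0997 and 0.890 ± 0.392 CPM; keratin pseudogenes can share reads. KRT18 also rose in T98G (81.8 ± 40.0 CPM) and LN-229 (52.0 ± 0.744 CPM). In LN-229 its level lies under the arithmetic mean of the other lines. The camera test called the list in LN-18 (adjusted p = 0.0309) and KALS-1 (adjusted p = 0.0294), and in neither with an estimated correlation (adjusted p = 0.509 for both). LN-18 was highest for the germline gene GTSF1 (57.9 ± 1.77 CPM), LINC01029 (45.9 ± 3.33 CPM), ADAMTS19 (41.3 ± 2.88 CPM), FAM95A (23.5 ± 0.0377 CPM) and the mucin gene MUC15 (21.6 ± 0.802 CPM). The mesenchymal transcription factor gene PRRX1 had 2 reads in LN-18 against 212 CPM over the other lines, and DHRS3 had 2.

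T98G was highest for ITGA8, an integrin gene (207 ± 87.7 CPM), TNFRSF11B, the osteoprotegerin gene (822 ± 469 CPM), TMEM52B (184 ± 104 CPM), the complement protease gene MASP1 (39.0 ± 20.1 CPM) and MPPED2 (32.2 ± 3.78 CPM), with adjusted p-values from 9.73e-17 to 1.34e-13. NTNG1, PLCB1 and BCHE had 0 reads, at least 531-fold, 429-fold and 272-fold below the mean of the other lines. MDM2 fell to 37.9 ± 9.39 CPM in T98G and rose to 174 ± 15.3 CPM in LN-229 and 139 ± 5.94 CPM in U-87MG. The T98G level was not particular to that line: the libraries of SNU-1105 were at 35.8 and 43.4 CPM and those of KALS-1 at 45.8 and 43.4 CPM. Libraries of LN-18, KNS-42 and U-138MG were higher, from 53.4 to 93.9 CPM. The median log2 difference of all tested genes in T98G was -1.03, so the fall of MDM2 was not set apart from that of the listed genes. TRIB3, a gene of the amino acid stress response, reached 401 ± 212 CPM in T98G. The 2 T98G libraries differed from each other more than those of other lines: 61.4% of genes lay within 1.5-fold in the pair, against 74.9% in SNU-1105 and at least 89.2% in each other line.

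Counts of higher genes by edgeR were 701 in U-138MG, 693 in U-87MG, 691 in KNS-42, 650 in LN-18, 584 in LN-229, 540 in SNU-1105, 504 in KALS-1 and 433 in T98G. Lower genes numbered 630 in T98G, 522 in LN-18, 408 in KALS-1, 340 in U-87MG, 335 in U-138MG, 286 in KNS-42, 252 in LN-229 and 184 in SNU-1105. These counts of lower genes can miss genes at 0 reads in another line, and limma on log2 CPM gave 997, 810, 761, 633, 627, 547, 554 and 436 in the same order. Called genes above every other library numbered from 62 in SNU-1105 to 297 in KNS-42, and those below from 27 in SNU-1105 to 188 in T98G. Chance gives 0.833% of genes if all libraries vary alike, and up to 12.5% if the libraries of a line go together. In T98G 40.7% of calls were higher with library totals, 55.2% with TMM and 56.3% with RLE factors. The share moved without crossing 50% under these scalings in the other lines, for example from 55.3% to 64.2% in KALS-1 and from 67.7% to 58.8% in U-138MG with TMM, and from 55.5% to 66.4% in LN-18 with RLE factors. With DESeq2 it was 46.6% in KALS-1 and 47.95% in LN-18, and with limma 37.4% and 41.7%, and 48.9% in LN-229. With TMM the median log2 difference of all genes moved by 0.58 in T98G, 0.34 in KALS-1, 0.32 in LN-18, -0.21 in LN-229, -0.31 in KNS-42, -0.32 in U-138MG and U-87MG, 0.11 in AM-38 and -0.13 in SNU-466.

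SNU-466 had high glial and matrix genes in the table of 3 lines, where 93.9% of the listed genes differ 2-fold or more between this line and the other 2. The calcium-binding glial protein gene S100B was at 1730.5 ± 0.458 CPM, the glial transcription factor gene SOX10 at 659 ± 26.3 CPM, the myelin gene MBP at 576 ± 6.11 CPM and the receptor gene ERBB3 at 520.3 ± 4.67 CPM, against at most 4.08 CPM for these in A-172 or AM-38. Of 9 astrocyte and oligodendrocyte genes, 7 rose and 2 fell, among them GLUL, the glutamine synthetase gene, to 0.0804 CPM (85.2 CPM in A-172). Of 9 proneural genes 7 rose and 2 fell. Neither list was called (camera adjusted p = 0.137 and 0.0712). ACAN, the aggrecan gene, was at 2646 ± 67.6 CPM with 2 reads in the other lines, COL11A1 at 7381 ± 95.2 CPM, COL1A2 at 10209 ± 16.0 CPM and the thrombospondin gene THBS1 at 10126 ± 218 CPM. Of 17 matrix genes 13 rose and 4 fell, COL6A3 among them (2.25 ± 0.155 CPM). Hypoxia genes rose in 5 of 6 cases, with P4HA1 at 762 ± 9.05 CPM and VEGFA at 312 ± 0.896 CPM, and interferon genes in 5 of 6, with IFI6 at 198 ± 7.62 CPM. The camera test called these 3 lists (adjusted p = 0.0445 each), none with an estimated correlation (adjusted p = 0.546 each). MAOB, the monoamine oxidase B gene, was at 203 ± 5.70 CPM and PMP2, a peripheral myelin gene, at 127 ± 5.15 CPM, at least 5480-fold and 3420-fold above the other lines, which had 0 reads. ITIH6 was at 338 ± 4.67 CPM and CPXM2 at 306 ± 5.78 CPM. EGFR was at 0.106 ± 0.0663 CPM in SNU-466 against 348 ± 3.97 CPM in A-172 and 462 ± 11.1 CPM in AM-38. The neprilysin gene MME and ANXA3 had 0 reads, at least 7297-fold and 1031-fold below the mean of the other lines, as had MAGEA10, which is uncertain because of its near-identical family.

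**Figure D3:**
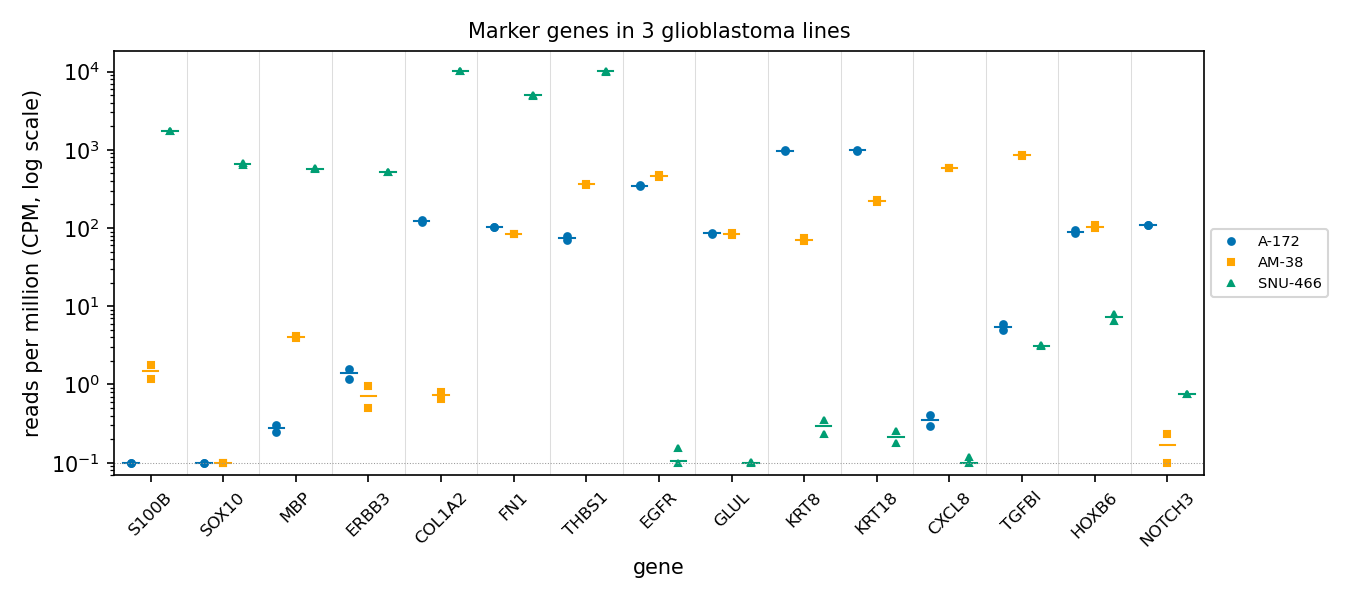
CPM (log scale) of 15 named genes in A-172, AM-38 and SNU-466, with 1 point per library and a short bar at the mean of the 2 libraries; values under 0.1 CPM are drawn at 0.1. S100B, SOX10, MBP and ERBB3 lie highest in SNU-466 (1730.5, 659, 576 and 520.3 CPM), where EGFR is at 0.106 CPM, while CXCL8 lies highest in AM-38 (589 CPM) and KRT18 in A-172 (983 CPM).

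AM-38 had high cytokine genes and low matrix genes. All 8 inflammatory cytokine genes rose, led by CXCL8, the interleukin 8 gene, at 589 ± 3.72 CPM, with IL1B at 36.0 ± 0.60 CPM and CXCL1 at 35.4 ± 2.30 CPM. The collagenase gene MMP1 was at 3132 ± 47.9 CPM and 0.630 CPM in SNU-466, and TGFBI, an adhesion protein gene, at 851 ± 24.4 CPM. The lipase inhibitor gene G0S2 (208 ± 9.07 CPM), FAM9A (90.7 ± 8.46 CPM) and ADGRD1-AS1 (59.2 ± 0.806 CPM) had 0 reads in the other lines, at least 5297-fold, 2306-fold and 1504-fold lower, and ADGRF5 (498 ± 14.6 CPM) and SERPINB2 (334 ± 0.620 CPM) had 3 and 2. Of 17 matrix genes 12 fell and 3 rose, with COL1A2 at 0.727 ± 0.105 CPM and COL4A1 at 12.7 ± 1.32 CPM. Of 9 classical glioblastoma genes 7 fell and EGFR rose, 5 of 9 proneural genes fell, and 4 of 6 interferon genes fell, with IFI6 at 2.93 ± 0.592 CPM. The rise of EGFR is against a log-scale mean that holds SNU-466 (0.059 and 0.153 CPM in its libraries). EGFR was at 454 and 470 CPM in the AM-38 libraries and at 346 and 351 CPM in those of A-172. IGFBP2 fell to 4 reads, and PDLIM3 had 0 reads, against 89.7 ± 4.14 CPM in SNU-466 and 2.04 ± 0.274 CPM in A-172. The camera test called the cytokine list (adjusted p = 0.0310) and the matrix, classical, proneural and interferon lists (adjusted p = 0.0445 each), none with an estimated correlation (adjusted p = 0.546 each). The classical list was not called without SNU-466 replicate 1 (adjusted p = 0.0675) or replicate 2 (adjusted p = 0.0658).

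A-172 was highest for KRT8, KRT18 and several other genes. KRT18 was at 983 ± 33.1 CPM and KRT8 at 974 ± 22.8 CPM, against 221 ± 12.6 and 71.2 ± 3.82 CPM in AM-38 and under 0.3 CPM in SNU-466. The genes UCHL1, encoding a deubiquitinase, and NEFL, encoding neurofilament light chain, were at 607 ± 5.06 and 403 ± 2.33 CPM, while of 7 neuronal genes 3 rose and 2 fell (camera adjusted p = 0.930, not called). Of 14 HOX genes 9 rose and 3 fell (camera adjusted p = 0.184, not called), with HOXB3, HOXB6 and HOXB8 at 127 ± 2.96, 90.1 ± 4.45 and 89.0 ± 1.59 CPM in A-172, 84.5 ± 1.07, 104 ± 6.47 and 6.47 ± 0.0567 CPM in AM-38, and 3.83 ± 0.415, 7.19 ± 1.07 and 2.79 ± 0.0568 CPM in SNU-466. The desmosome gene PKP2 (94.7 ± 1.57 CPM) and MALL (64.4 ± 3.26 CPM) had 5 reads and 1 read in the other lines; CLIC3 (56.2 ± 1.65 CPM) and PALM3 (22.5 ± 0.0174 CPM) had 0, at least 1456-fold and 582-fold lower. NOTCH3 reached 109 ± 0.195 CPM, and SUCNR1, the succinate receptor gene, 594 ± 64.4 CPM. The endothelin receptor gene EDNRB and SEMA6D had 0 reads, against 71.98 ± 4.70 and 105 ± 1.77 CPM in SNU-466 and 1.58 ± 0.171 and 1.05 ± 0.0121 CPM in AM-38, and TMEM47 had 2 reads. Of 6 hypoxia genes 4 fell, with VEGFA at 50.8 ± 4.25 CPM and NDRG1 at 24.4 ± 1.66 CPM (camera adjusted p = 0.0445; adjusted p = 0.546 with an estimated correlation).

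Genes of glioblastoma drivers and of the response to temozolomide also differed among these 3 lines. NF1 was at 37.8 ± 1.19 CPM in SNU-466, 149 ± 7.90 CPM in AM-38 and 213 ± 4.11 CPM in A-172. MGMT, encoding the enzyme that removes alkyl groups from guanine, was at 11.5 ± 0.552 CPM in SNU-466, and A-172 had 2 reads and AM-38 none. CDK6 stood at 371 ± 3.58 CPM in SNU-466, 319.9 ± 27.9 CPM in A-172 and 134 ± 6.89 CPM in AM-38, and TERT at 1.70 ± 0.816 CPM in A-172, 1.16 ± 0.155 CPM in AM-38 and 0.198 ± 0.136 CPM in SNU-466. The TERT call in AM-38 was not kept with DESeq2 or limma.

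Of 5035 tested genes, 4939 differed among A-172, AM-38 and SNU-466 (edgeR, with line means at least 1 apart on the log2 scale; 5035 by the adjusted p alone), and the line means of 3707 spanned at least 2 on the log2 scale. SNU-466 had 1951 higher and 2779 lower genes, AM-38 1802 and 1286, and A-172 1561 and 854; limma on log2 CPM gave 1299 lower genes in A-172. If the listed genes were chosen on the difference of SNU-466 from the other lines, its counts follow in part from that choice. Of the higher genes, 1951 in SNU-466, 1379 in AM-38 and 1053 in A-172 lay above every other library; chance gives 6.67% of genes if all libraries vary alike, and up to 33.3% if the libraries of a line go together. A line was set against the mean of only 2 others, so calls in one line lower or raise those in the others. With the replicate number as a block, 1 of the 9 lists called in these lines was called, and the other 8 had an adjusted p of 0.0531.

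Camera called 4 of 88 list tests in the 8 lines and 9 of 60 in the 3 lines; the median, mean and direction of each of these lists shared a sign. Adjusted over the list alone, member counts were the same as over all genes for these lists, except that 2 interferon genes rather than 1 rose in U-87MG. The listed genes held 13 of 20 interferon genes in the 8-line table, more than the share of the other lists (57 of 352 genes). They held 17 of 24 matrix genes in the 3-line table (128 of 348 genes of the other lists). Fisher's exact test, two-sided and not planned, gave adjusted p = 8.47e-05 and 0.0215 for these, over 24 lists. Of 22 cell cycle genes, 0 were listed in either table (adjusted p = 0.118 and 0.000385).

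Culture medium was compared between the EMEM lines (T98G, U-138MG, U-87MG) and the DMEM lines (KNS-42, LN-18, LN-229), with the line as the replicate (3 against 3). The smallest p belonged to RGMA, a guidance receptor ligand gene at 96.3 CPM in KNS-42, 16.2 CPM in LN-229 and 0.412 CPM in LN-18, and at or under 0.0278 CPM in the EMEM lines (log2 fold change -10.84, SE 2.55, adjusted p = 0.432). Across all genes, edgeR called 0 of 2005 genes, with 209 at an unadjusted p under 0.05, and DESeq2 called 159. Each medium was used for different lines, and in simulated data with the spread of these lines the test recovered 0 of 100 genes changed 64-fold.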

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

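Tests of TMM factors on the listed genes, limma on log2 CPM and a fit without T98G were chosen after the data were seen; the other alternatives were planned. Of the alternatives run, none reversed the direction of a named gene or called list. Counts of higher and lower genes per line stayed within 1.5 times under TMM and RLE factors, DESeq2, no low-count filter, the replicate block, each library left out and the fit without T98G. With a library left out, the low-count filter by line let in more genes, so the number of genes differing among lines cannot be compared with that of the main fit. Of the calls per line, at least 81.8% were kept with TMM and 81.0% with RLE factors (both lowest in T98G), 92.4% with DESeq2, 98.3% with the replicate block, 87.7% with limma and 80.8% with a library left out.

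Counts of lower genes rose with limma to 761 in KALS-1, 547 in KNS-42, 810 in LN-18, 554 in LN-229, 436 in SNU-1105, 997 in T98G, 627 in U-138MG, 633 in U-87MG and 1299 in A-172. The edgeR contrast has no finite value for genes at 0 reads in another line, and such genes with a p above 0.9 numbered 246 to 359 per line in the 8-line table, near the rise in most lines, and 179 in A-172, fewer than the rise. The test and the prior count changed together, so the cause was not tested.

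With the filter at 5 CPM, which tests fewer genes, 1376 genes differed among the 8 lines; higher genes were 277 in KALS-1, 354 in LN-18, 267 in T98G, 987 in A-172 and 1099 in AM-38, and lower genes 1816 in SNU-466. The fit of all 11 lines was limited to 779 genes and compared each line with 10 others. There 771 genes differed among the 8 lines and 766 among the 3, with higher and lower genes of 168 and 201 in KALS-1, 273 and 151 in KNS-42, 209 and 230 in LN-18, 282 and 110 in LN-229, 260 and 73 in SNU-1105, 147 and 289 in T98G, 297 and 142 in U-138MG, 291 and 133 in U-87MG, 245 and 188 in A-172, 316 and 205 in AM-38, and 321 and 428 in SNU-466.

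Gene list calls depended most on the test. An estimated correlation called 0 lists in each table, against 4 and 9 with the preset correlation. The classical list in AM-38 lost its call although its estimated correlation (-0.0114) was under the preset 0.01. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the many genes. The lost calls can thus not be laid to correlation between genes alone, and the parts were not tested apart. The fry test, which sets a list against no change rather than against the other genes, called 73 and 54. With the replicate block 4 lists were called in the 8-line table and 1 in the 3-line table, and the other 8 had an adjusted p of 0.0531; the cause was not tested. Without a library, 4 to 6 lists were called in the 8-line table and 8 to 11 in the 3-line table. DESeq2 called 159 genes between EMEM and DMEM where edgeR called 0, also with TMM or RLE factors, either filter and each line left out; the cause was not tested.

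Named genes and called list members were checked for direction and an adjusted p under 0.05, not for the size of the change. With a library left out, none of them reversed direction. Those that lost an adjusted p under 0.05 numbered 6 with TMM, 7 with RLE factors, 5 with DESeq2, 6 with limma and 1 with the replicate block, of 712 each. They numbered 1 in the fit of all 11 lines (238 kept), 3 without T98G (320 kept), and 0 with no filter or the filter at 5 CPM. TERT in AM-38 was not called by DESeq2 (adjusted p = 0.116) or limma (adjusted p = 0.0764). A line left with 1 library was assumed to vary like the others. Deviations of libraries from their line mean correlated between lines at r of -0.135 to 0.0925 in 28 pairs of the 8 lines and -0.0453 to 0.0790 in 3 pairs of the 3 lines. Libraries of the same replicate number thus showed no strong common deviation over the listed genes. Whether they share a day or batch is not stated and cannot be told from these values.

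Not run were the 3 relations of gene lists across lines with their alternatives, for the reason given with the methods, and another pseudocount, since counts were tested. Depth limits genes near 0: 3 reads in a library are 0.141 to 0.177 CPM, and levels under that are not distinguished from 0.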

Other observations

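Cancer-testis antigen genes fell in SNU-466 in 7 of 7 cases (camera adjusted p = 0.0633, not called) and rose in 5 cases in AM-38 and 4 in A-172. PRAME was at 73.9 ± 5.22 CPM in A-172 and 0.0753 CPM in AM-38, and PAGE5 at 67.5 ± 2.54 CPM in AM-38; the MAGEA genes, which also rose, are uncertain because of near-identical copies. Of 4 pericyte and smooth muscle genes, 3 rose and 1 fell in SNU-466. ACTA2 was at 205 ± 4.02 CPM and TAGLN at 36.3 ± 0.511 CPM in SNU-466, while RGS5, a pericyte gene, was at 41.3 ± 2.61 CPM in A-172 and 0.887 ± 0.246 CPM in SNU-466. This list was called in no line (camera adjusted p = 0.384 in SNU-466, 0.423 in A-172 and 0.514 in AM-38). The endothelial receptor gene TEK was at 9.94 ± 1.02 CPM in A-172, with 0 reads in SNU-466.

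In the 8 lines, the melanocyte transcription factor gene MITF was at 60.4 ± 0.138 CPM in LN-18 and 48.3 ± 2.54 CPM in KALS-1, and the pigment gene TYRP1 at 16.0 ± 0.479 and 2.88 ± 0.689 CPM. MITF was also at 50.2 and 36.7 CPM in the LN-229 libraries. DCT, the remaining gene of the 3 tested, was at or under 0.153 CPM in each library of LN-18 and KALS-1. The melanocyte list was called in neither line (camera adjusted p = 0.451 and 0.635). HOXA13 was at 37.5 ± 4.57 CPM in KALS-1 with 0 reads in U-87MG, and HOXB2 at 41.6 ± 1.21 CPM in KNS-42, 40.3 ± 1.82 CPM in SNU-1105 and 22.9 ± 0.406 CPM in U-87MG. The macrophage receptor gene CSF1R was at 24.4 ± 2.58 CPM in SNU-1105.

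All tests below were chosen after the results were seen. Genes with the largest ratios in the T98G pair included HYOU1 at 3671 CPM in replicate 1 and 1068 CPM in replicate 2, CRELD2 at 781 and 221.8 CPM and IL6ST at 1932 and 620.7 CPM, while FN1 was at 476.3 and 1546 CPM and the peroxiredoxin gene PRDX1 at 915.5 and 2189 CPM. The share of genes within 1.5-fold in this pair, 61.4%, was 61.2% with libraries thinned to the lowest total and 62.4% after dividing out the median ratio, below every other line in each case, which argues against depth and scaling. RNA of 9 other lines is argued against by a median share of at most 0.12% in either library, and RNA of LN-18 by 9 genes at 20 CPM or more in LN-18 that stand under 1% of that level in both T98G libraries, GTSF1 with 0 reads among them. No biological explanation was tested, and the labels give the libraries no difference.

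The median log2 difference of the 13 interferon genes in KALS-1 was 5.60, and TMM factors shift all genes there by 0.344, which argues against scaling. RNA of antigen-presenting immune cells would bring CD74 and HLA-DRA, which stood at 0.233 and 0.0255 CPM in KALS-1, although PTPRC (5.96 CPM) and CD14 (10.4 CPM) were present. These values argue against such cells, and a difference between the lines stays open, as untested.

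Between EMEM and DMEM edgeR called 0 genes, with 209 at an unadjusted p under 0.05, and DESeq2 called 159. All 10 splits of the 6 lines into 3 and 3 called 0 by edgeR, the highest of the others included, with up to 434 genes at an unadjusted p under 0.05. Those 10 splits are too few for a share under 0.05.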
